A study of Nakaseomyces glabratus with 6 samples.

How the data were processed

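Messenger RNA was sequenced from wild-type Candida glabrata CBS138, a pathogenic yeast now named Nakaseomyces glabratus, after exposure to the drug eltrombopag or to its solvent DMSO. Per the labels' protocols, cells from an overnight culture at 30 °C in rich medium were moved to RPMI 1640, grown at 37 °C for 3 h, and then exposed for 3 h at 37 °C. RNA was extracted with TRIzol and glass beads, and libraries were made with a stranded TruSeq mRNA kit. The labels give 3 samples per group. They do not state whether the 3 came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

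The authors deposited estimated counts per transcript for the 6 libraries, in a table whose name and headers give RSEM as the counter. The submitters' processing notes name fastp 0.23.2, Bowtie2, RSEM and edgeR 3.22.5, without their order or settings. The genome build and annotation are not given in the sources used here, nor is the strand setting of the counting, so counts of overlapping and antisense genes are uncertain. Of the deposited estimated count values, 97.3% were whole to within 0.005. Among the transcripts kept for testing, 150 had values that were not whole. RSEM had divided their reads among near-identical sequences, and values of these genes are uncertain. The lengths deposited by the authors, per the file headers, were read as coding lengths. Those of protein-coding transcripts are multiples of 3, and those of ribosomal RNA entries were not checked for this. The same table holds 12 columns of TPM and FPKM, which were not used here. A second table holds the authors' own comparison, with log2 fold changes deposited for 5281 genes, and p-values and false discovery rates deposited beside them. Its headers name the sides of that comparison only as A and B, and the deposited counts show that A is eltrombopag and B is DMSO. Columns of the count table carry a letter and a number, C or T with 1 to 3, which were read as the control and treatment titles of the labels.

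All 5290 transcripts matched RefSeq's table for assembly ASM1011175v1, which was used only for gene symbols, locus tags and neighbouring genes, and 4557 had a symbol. A symbol carried by more than 1 entry is followed by its locus tag. Most symbols are those of baker's yeast genes, and what a gene is known to do is background from the baker's yeast gene of that name. Of the transcripts, 32 are ribosomal RNA. They held 0.124 to 0.254% of the counts per library, and 24 of them passed the filter and stayed in the test.

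Estimated counts were rounded to whole numbers and summed to 7159111, 22562918 and 20794156 in DMSO 1 to 3 and to 23750455, 24256427 and 21721341 in eltrombopag 1 to 3 before rounding. Counts were scaled by edgeR's TMM factors, which lay between 0.853 and 1.15, and filtered with filterByExpr at a minimum count of 10, which left 5187 genes and removed 103. The groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene is said to have risen or fallen where its adjusted p was under 0.05. Standard errors of the log2 fold changes were approximated as the fold change divided by the square root of its F statistic. Levels are CPM, computed with TMM factors, as mean ± SD of 3 libraries. The biological coefficient of variation was 21.7%. In counts simulated from these libraries' means for 5187 genes, the same test recovered 63% of genes changed by 1 on the log2 scale and 98% of those changed by 2, with 3.03% false calls. DESeq2 recovered 76% and 97%, with 12.2% false calls, and limma-voom 65% and 98%, with 2.41%. These simulated genes varied independently, without the shared shifts between libraries described below, and far fewer of them were changed than were called in the data. The percentages therefore need not hold for the real calls.

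Gene lists, the rule for named genes, the test and the other settings named below as chosen in advance were fixed before the data were examined. There were 43 lists, matched by symbol, of which 42 had at least 5 tested members. A gene may belong to more than 1 list. Each list was compared with all other tested genes by camera with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data. Of 23 lists past the threshold with the preset value, 0 were past it with the estimated one, where the smallest adjusted p was 0.0522. Every list result is therefore given with both. In the simulated counts the estimated version missed a list shifted by 0.5 on the log2 scale (adjusted p = 0.247 with camera) and found one shifted by 1.5 (adjusted p = 0.000794 with camera), a size added after the first result had been seen. The preset version found both, and neither called any of 30 unchanged lists. Simulated genes were drawn independently of each other. These results therefore do not show how either version behaves where genes of a list vary together.

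Named genes are the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean of at least 10 CPM, groups that do not overlap and a symbol, with at most 2 identifiers without a symbol per direction. Added to these are up to 4 members per list with the largest absolute change among those past the threshold, and a fixed panel of PDR1, CDR1, PDH1, SNQ2, ERG11, ERG1, ERG3, UPC2A, AFT1, FET3, FTR1, SIT1, HMX1, CTH2, CCC1, CTA1, EPA1, FKS1 and FKS2. No entry carried the symbols UPC2A, SIT1, CTH2 or FKS2. Whether these genes are present under other symbols was not checked. Other genes are named where they make up a small count, or where they are exceptions within a list, and these were chosen after their values were seen. A gene that the rule names is not reported here.

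Settings chosen in advance were DESeq2 1.42.0, limma-voom, RLE factors, library size without TMM factors, no filter on low counts, a filter of at least 10 CPM in 3 libraries, counts left unrounded, the replicate number as a block, the omission of each library in turn, and for the lists an estimated correlation and the fry test. Added after the data were seen were a fit that counts eltrombopag 2 and 3 as 1 sample and a fit with the split of the libraries along the second principal component as a covariate. That split was taken from the same counts, so p-values of the covariate fit may be too small. A setting meant for a table without counts did not apply. Principal components were computed from log2 CPM with a prior count of 2. Figures were drawn with matplotlib 3.10.9.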

Results

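RNA sequencing of wild-type Candida glabrata CBS138 compared cells exposed for 3 h to 1 mg/L eltrombopag, which the labels give as 4 times the minimal inhibitory concentration, with cells given the same volume of DMSO. Eltrombopag is an oral thrombopoietin receptor agonist that is also known to bind iron. The comparison asks which transcripts change when this yeast is exposed to the drug. Each group had 3 libraries. Total estimated counts were 7159111 in DMSO 1 and between 20794156 and 24256427 in the other 5 libraries, so values of DMSO 1 carry the most counting error.

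Under eltrombopag, 22 of 25 ergosterol synthesis genes and 17 of 19 iron uptake genes rose, and 26 of 35 iron-sulfur genes and 27 of 34 respiration genes fell. Of 5187 genes tested, 777 rose and 866 fell by edgeR's quasi-likelihood test, and 656 of these changed at least 2-fold, 243 up and 413 down. The 12 largest rises among genes with a symbol were those of TIR3, SET4, ATH1, TIR2, HMX1, GRX4, UPC2, HES1, SOK2, PBI1, ARN1 and FMP23. TIR3 (GVI51_C03663), a cell wall mannoprotein gene, rose from 10.2 ± 6.00 to 744 ± 133 CPM (SD, n = 3), a log2 fold change of 6.24 ± 0.48 (SE, edgeR adjusted p = 0.000269). ATH1, which encodes acid trehalase, rose from 574 ± 66.0 to 12510 ± 1356 CPM, and SET4, a SET domain protein gene, from 19.7 ± 2.63 to 585 ± 188 CPM. Among the largest falls were those of CCP1, RLI1, CIR2, YAT1, ACS1, HIS3, LEU4, ILV3, YMC2, ACO1 and LEU1. CCP1 (GVI51_K08041), which encodes the heme enzyme cytochrome c peroxidase, fell from 645 ± 69.3 to 17.2 ± 3.24 CPM, a log2 fold change of -5.23 ± 0.20 (SE, edgeR adjusted p = 5.83e-05). RLI1, an iron-sulfur protein that acts in ribosome recycling, fell from 81.6 ± 25.6 to 3.76 ± 1.21 CPM, and YAT1, a carnitine acetyltransferase gene, from 1138 ± 311 to 57.0 ± 8.45 CPM. Among genes without a symbol, GVI51_M05335 rose by 5.83 ± 0.15 on the log2 scale and GVI51_C03003 changed by -5.24 ± 0.44. GVI51_H09515 rose by 7.22 ± 0.98, but its reads are shared with a similar sequence. ACS1, an acetyl-CoA synthetase gene, had 7237, 457 and 2933 CPM in DMSO 1, 2 and 3 and 191 ± 58.8 CPM in eltrombopag. Its log2 fold change of -4.21 ± 0.94 became -3.13 without DMSO 1 and -2.918 with the covariate, and it lost its call without eltrombopag 2 (edgeR adjusted p = 0.0645) or eltrombopag 3 (edgeR adjusted p = 0.0625).

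Groups did not overlap in 1637 of the 1643 genes called and in 48.9% of all genes tested, against 10% by chance for 3 libraries against 3. In the plot of principal components, the first component (69.8% of variance) separated the groups. The second (20.6%) separated DMSO 2, eltrombopag 2 and eltrombopag 3 from DMSO 1, DMSO 3 and eltrombopag 1. These sets hold unequal shares of the treatments, so part of their difference can enter the fold changes between groups. The permease gene GAP1 changed by -2.00 on the log2 scale within DMSO 1, DMSO 3 and eltrombopag 1, and by -0.51 within the other set. Across called genes, fold changes within the sets correlated at 0.951. Eltrombopag 2 and 3 differed by a coefficient of variation of 4.53% per gene, against 15.5 to 27.1% for the other pairs within a group. Their difference was 2.78 times counting noise, which repeat preparations of the same culture could also give, so whether they are separate samples remains open. They were kept apart as labelled. Counted as 1 sample, 360 genes rose and 476 fell. Leaving out a library moved the counts of rising and falling genes by over 1.5 times without eltrombopag 2 (350 and 456) or eltrombopag 3 (359 and 483), and that of rising genes alone without DMSO 1 (444, with 600 falling). Scaling by library size alone moved the median log2 fold change of all genes from -0.013 to -0.16, and relative to it 333 genes rose and 938 fell, so that 26.2% of the calls were rises, against 47.3% with TMM factors.

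**Figure D1:**
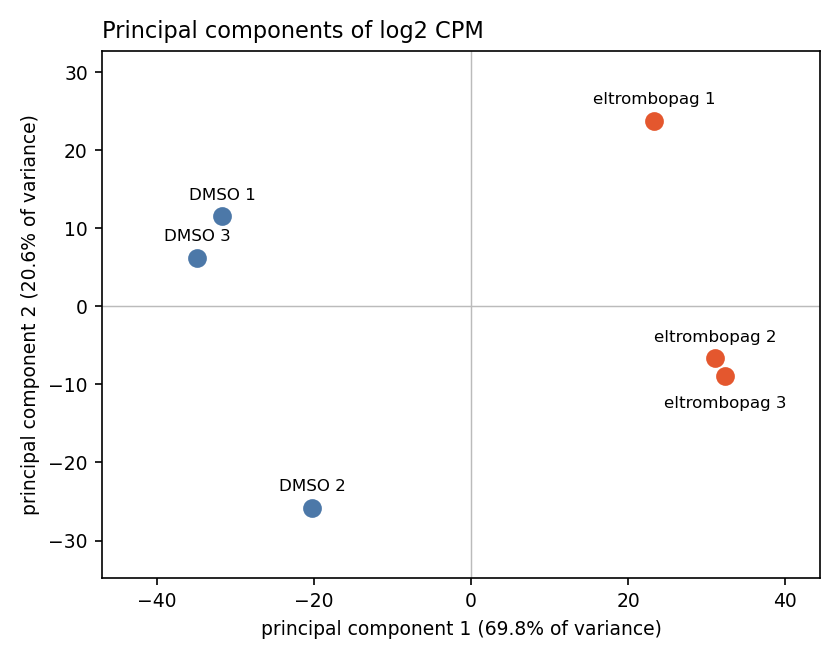
Principal components of log2 CPM, with 1 point per library, blue for DMSO and red for eltrombopag. The first component (69.8% of variance) separates the groups, and the second (20.6%) places DMSO 2, eltrombopag 2 and eltrombopag 3 below 0 and the other 3 libraries above it.

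Genes of ergosterol synthesis, the pathway that makes the main fungal sterol, rose together. Of 25 members tested, 22 rose, 1 fell and 2 were not past the threshold, and adjusted over the list alone 23 rose and 1 fell. The median log2 fold change was 1.82 (camera adjusted p = 6.55e-12, and adjusted p = 0.171 with an estimated correlation). ERG11, the lanosterol demethylase that azole drugs inhibit, rose from 167 ± 24.4 to 1498 ± 510 CPM, a log2 fold change of 3.16 ± 0.30 (SE, edgeR adjusted p = 0.000636). ERG3, the sterol C-5 desaturase, rose by 3.08 ± 0.17 on the log2 scale, ERG13, the HMG-CoA synthase, by 3.08 ± 0.20, NCP1, the reductase that passes electrons to ERG11, by 2.47 ± 0.16, and ERG1, the squalene epoxidase, by 2.13 ± 0.16. IDI1, the isopentenyl diphosphate isomerase, was the member that fell (-0.48 ± 0.12), which 0 members did with library size alone, and ERG5 and ERG24 had log2 fold changes of 1.04 ± 0.43 and 0.29 ± 0.26 (edgeR adjusted p = 0.107 and 0.431). In the list of sterol uptake and its regulators, 6 of 10 members rose and 0 fell, and adjusted over the list alone 8 rose (median 0.95, camera adjusted p = 0.000122, and adjusted p = 0.175 with an estimated correlation). UPC2, a transcription factor of sterol genes, rose from 10.3 ± 1.28 to 139 ± 43.2 CPM, and AUS1, a sterol importer gene, from 40.6 ± 8.92 to 211 ± 49.2 CPM. Whether this UPC2 entry is the gene called UPC2A in this species was not checked. TIR2, whose reads are partly shared with similar genes, changed by 4.18 ± 0.34 on the log2 scale.

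Iron uptake genes rose. In the list of high-affinity iron uptake and targets of the regulator Aft1, 17 of 19 members rose, 1 fell and 1 was not past the threshold, with the same counts adjusted over the list alone (median log2 fold change 1.17, camera adjusted p = 4.18e-09, and adjusted p = 0.0522 with an estimated correlation). ARN1, a siderophore transporter gene, rose from 795 ± 66.2 to 8200 ± 464 CPM, a log2 fold change of 3.37 ± 0.14 (SE, edgeR adjusted p = 6.28e-05). The regulator AFT1 rose by 1.87 ± 0.15, the iron permease gene FTR1 by 1.48 ± 0.15, the multicopper ferroxidase gene FET3 by 1.05 ± 0.21 and the low-affinity transporter gene FET4 by 2.30 ± 0.14. AFT2, a paralog of AFT1, was the member that fell (-0.88 ± 0.15), and the ferric reductase gene FRE8 had a log2 fold change of 0.56 ± 0.93. HMX1, a heme oxygenase gene, rose by 3.99 ± 0.95 but varied within groups, at 33.8 ± 26.0 CPM in DMSO and 528 ± 544 CPM in eltrombopag, and its log2 fold change was 2.703 without eltrombopag 1. It lost its call without DMSO 3 (edgeR adjusted p = 0.0801).

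Most genes for iron-sulfur cluster assembly and iron-sulfur enzymes fell. Of 35 members, 26 fell, 2 rose and 7 were not past the threshold, and adjusted over the list alone 27 fell and 2 rose (median log2 fold change -1.53, camera adjusted p = 4.43e-10, and adjusted p = 0.0522 with an estimated correlation). Besides RLI1, large falls were those of ILV3, the dihydroxyacid dehydratase of branched-chain amino acid synthesis (-3.79 ± 0.20), and ACO1, aconitase (-3.59 ± 0.40). The members that rose were GRX4, a glutaredoxin that takes part in iron sensing (3.82 ± 0.19), and ISU1, the scaffold of cluster assembly (1.07 ± 0.25), both also members of the iron uptake list, and with library size alone 1 member rose. Of 7 members of the list of vacuolar iron storage and Yap5, 5 rose and 2 fell, also when adjusted over the list alone (median 1.35, camera adjusted p = 0.0434, and adjusted p = 0.281 with an estimated correlation). The members that fell were CCC1, which carries iron into the vacuole (-1.62 ± 0.27), and TYW1, an iron-sulfur enzyme of tRNA modification (-2.19 ± 0.15). Those that rose were GRX4, the regulator YAP5 (2.22 ± 0.14), and FTH1, SMF3 and FET5, known for vacuolar iron export. All of these except YAP5 are also counted among the iron uptake genes that rose. The vacuolar storage list lost its call without DMSO 2 (camera adjusted p = 0.0832) or DMSO 3 (camera adjusted p = 0.0556), with the filter of 10 CPM (0.055), with the replicate block (0.0576) and with the split of the libraries as a covariate (0.055).

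Among 18 genes of heme synthesis and heme proteins, 12 fell, 2 rose and 4 were not past the threshold, and adjusted over the list alone 13 fell and 2 rose (median log2 fold change -1.20, camera adjusted p = 0.000122, and adjusted p = 0.171 with an estimated correlation). CTA1, the catalase gene, fell from 1631 ± 408 to 198 ± 18.0 CPM, a log2 fold change of -3.04 ± 0.22 (SE, edgeR adjusted p = 0.000223). The members that rose were HMX1, which breaks heme down, and DAP1, a heme-binding protein gene (0.70 ± 0.17). HMX1 lost its call without DMSO 3, where its adjusted p in edgeR was 0.0801, and with library size alone 1 member rose.

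Respiration genes fell. Of 34 members of the electron transport chain and ATP synthase list, 27 fell, 0 rose and 7 were not past the threshold, and adjusted over the list alone 29 fell (median log2 fold change -1.99, camera adjusted p = 2.78e-16, and adjusted p = 0.175 with an estimated correlation). COR1, a core subunit of complex III, fell from 1415 ± 141 to 184 ± 3.72 CPM (log2 fold change -2.95 ± 0.13, edgeR adjusted p = 6.28e-05), and the succinate dehydrogenase subunit genes SDH3 and SDH4 changed by -2.92 ± 0.15 and -3.04 ± 0.16. CYT1, cytochrome c1, changed by -3.11 ± 0.63 and lost its call without eltrombopag 2 (edgeR adjusted p = 0.0504). Among 18 members of the tricarboxylic acid cycle list, 9 fell, 2 rose and 7 were not past the threshold, with the same counts adjusted over the list alone (median -0.93, camera adjusted p = 0.00529, and adjusted p = 0.307 with an estimated correlation). CIT1, citrate synthase, fell from 5388 ± 781 to 953 ± 149 CPM, and ACO1 from 2738 ± 873 to 228 ± 98.5 CPM. The members that rose were LAT1, a pyruvate dehydrogenase subunit gene (0.54 ± 0.13), and LSC2, a succinyl-CoA ligase subunit gene (0.42 ± 0.12), and with library size alone 0 rose.

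In the list of gluconeogenesis, the glyoxylate cycle and acetate use, 9 of 19 members fell, 2 rose and 8 were not past the threshold, and adjusted over the list alone 11 fell and 2 rose (median log2 fold change -0.99, camera adjusted p = 0.000475, and adjusted p = 0.467 with an estimated correlation). The carnitine acetyltransferase genes YAT1, CAT2 and YAT2 changed by -4.32 ± 0.26, -3.32 ± 0.31 and -3.23 ± 0.43. The members that rose were FBP1, fructose-1,6-bisphosphatase (0.58 ± 0.16), and MDH3, a malate dehydrogenase gene (0.51 ± 0.11), and with library size alone 0 rose and 11 fell. This list's median lay between -1.214 and -0.554 across the alternatives. Of 17 glycolysis and fermentation genes, 3 rose, also when adjusted over the list alone, 0 fell and 14 were not past the threshold (median 0.32, camera adjusted p = 0.0187, and adjusted p = 0.482 with an estimated correlation). These 3 were TDH3 (0.68 ± 0.17), GLK1 (GVI51_F00473) (0.62 ± 0.14) and CDC19 (0.54 ± 0.12), genes of glyceraldehyde-3-phosphate dehydrogenase, glucokinase and pyruvate kinase. Each lost its call without DMSO 1 (edgeR adjusted p = 0.0565 to 0.0771), eltrombopag 2 (0.0886 to 0.0899) or eltrombopag 3 (0.07 to 0.0811), and TDH3 and GLK1 (GVI51_F00473) also without DMSO 3 (0.0593 and 0.0867). With library size alone only TDH3 rose, and the median was 0.169. The glycolysis list itself lost its call with DESeq2 (camera adjusted p = 0.0727) and without DMSO 2 (0.0735) or eltrombopag 1 (0.0689).

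**Figure D2:**
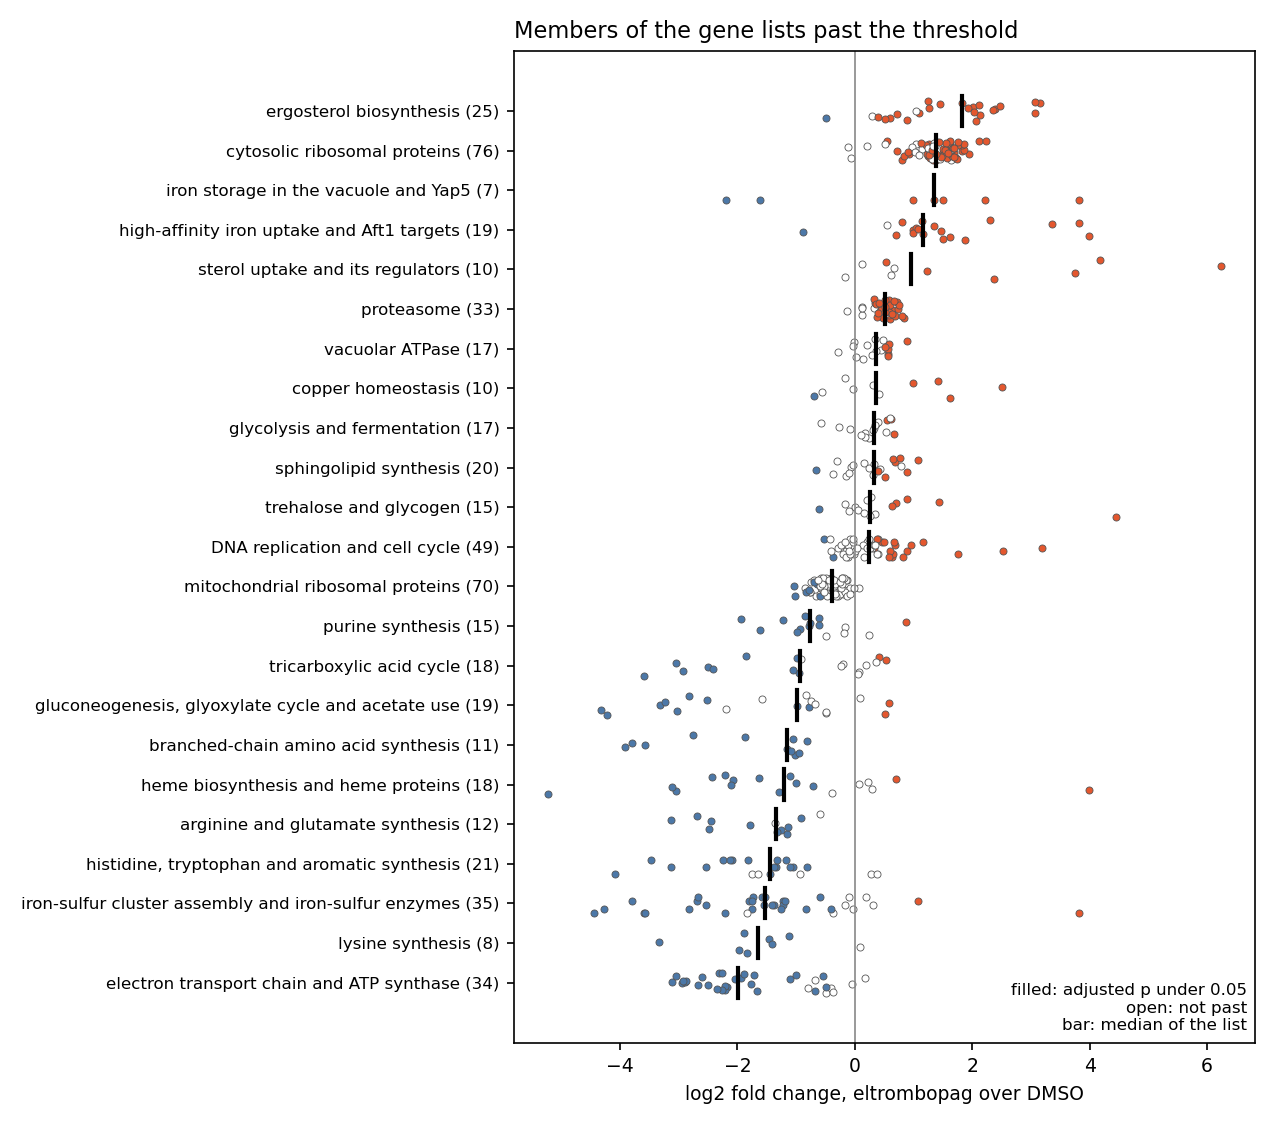
Log2 fold changes (eltrombopag over DMSO) of the members of the 23 gene lists past the threshold with a preset correlation, with 1 point per gene, filled where the adjusted p was under 0.05, and a bar at each list's median. Medians run from -1.99 for the electron transport chain and ATP synthase to 1.82 for ergosterol biosynthesis, and with an estimated correlation 0 of these lists passed.

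Amino acid synthesis genes fell in each of 4 lists. In branched-chain synthesis all 11 members fell, also when adjusted over the list alone (median log2 fold change -1.16, camera adjusted p = 1.27e-07, and adjusted p = 0.171 with an estimated correlation). LEU4, which encodes isopropylmalate synthase, fell from 7377 ± 3143 to 492 ± 54.3 CPM (log2 fold change -3.90 ± 0.38, edgeR adjusted p = 0.000683), and LEU1, the iron-sulfur enzyme of the next step, from 1026 ± 81.5 to 86.2 ± 19.5 CPM. In arginine and glutamate synthesis 10 of 12 fell and 0 rose, and adjusted over the list alone 11 fell (median -1.34, camera adjusted p = 5.8e-07, and adjusted p = 0.175 with an estimated correlation), with GDH3, a glutamate dehydrogenase gene, at -3.13 ± 0.36 and GLT1, glutamate synthase, at -2.70 ± 0.31. In lysine synthesis 7 of 8 fell, also when adjusted over the list alone (median -1.64, camera adjusted p = 8.46e-05, and adjusted p = 0.307 with an estimated correlation), led by LYS21, a homocitrate synthase gene (-3.34 ± 0.25), and LYS5 had a log2 fold change of 0.10 ± 0.14. In histidine, tryptophan and aromatic synthesis 16 of 21 fell and 0 rose, and adjusted over the list alone 18 fell (median -1.43, camera adjusted p = 4.59e-08, and adjusted p = 0.307 with an estimated correlation), led by HIS3 (-4.08 ± 0.41), ARO3 (-3.48 ± 0.21) and HIS4 (-3.12 ± 0.23). Of 15 purine synthesis genes, 10 fell, 1 rose and 4 were not past the threshold, with the same counts adjusted over the list alone (median -0.76, camera adjusted p = 0.00207, and adjusted p = 0.229 with an estimated correlation). ADE4, the first enzyme of the pathway, changed by -1.93 ± 0.14, and GUA1, which makes GMP, was the gene that rose (0.87 ± 0.22), and with library size alone 0 rose.

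Among 27 sulfur and methionine genes, 7 fell, 2 rose and 18 were not past the threshold, with the same counts adjusted over the list alone, and the list did not pass (median log2 fold change -0.21, camera adjusted p = 0.182, and adjusted p = 0.591 with an estimated correlation). MET28, a regulator gene, changed by -2.37 ± 0.33 and MET5, a sulfite reductase subunit gene, by -1.80 ± 0.20, and SAM2 (0.89 ± 0.27) and SAH1 (0.78 ± 0.15), genes of the methyl cycle, rose, while with library size alone 0 rose and 8 fell. Of 14 amino acid transport genes, 5 fell and 1 rose, and adjusted over the list alone 6 fell and 1 rose (camera adjusted p = 0.408, and adjusted p = 0.833 with an estimated correlation). Of 16 targets of nitrogen catabolite repression, 4 fell and 1 rose, and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.183, and adjusted p = 0.736 with an estimated correlation). The permease genes PUT4 (-1.54 ± 0.26) and GAP1 (-1.70 ± 0.44) fell in both lists, with DIP5 (-1.73 ± 0.36), GNP1 and AGP2 in the first and CAR1 (-1.16 ± 0.30) and DUR3 (GVI51_K02981) (-1.11 ± 0.30) in the second. The genes that rose were BAP3, a branched-chain amino acid permease gene (1.89 ± 0.34), and PUT1, proline oxidase (0.83 ± 0.19). Without eltrombopag 2, the calls of DIP5, GAP1, CAR1 and DUR3 (GVI51_K02981) were lost (edgeR adjusted p = 0.0571, 0.0899, 0.0636 and 0.0788), and those of DIP5, GAP1 and DUR3 (GVI51_K02981) without eltrombopag 3 (0.0541, 0.0796 and 0.0992). GAP1 and DUR3 (GVI51_K02981) also lost theirs without DMSO 3 (0.0617 and 0.0833) or eltrombopag 1 (0.0706 and 0.0788), and CAR1 and DUR3 (GVI51_K02981) without DMSO 1 (0.0802 and 0.0712). CAR1 further lost its call without DMSO 2 (edgeR adjusted p = 0.0505).

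Cytosolic ribosomal protein genes rose. Of 76 members, 56 rose, 0 fell and 20 were not past the threshold, and adjusted over the list alone 66 rose (median log2 fold change 1.39, camera adjusted p = 8.53e-16, and adjusted p = 0.467 with an estimated correlation). RPS3 rose from 48.9 ± 24.9 to 228 ± 31.5 CPM (log2 fold change 2.23 ± 0.39, edgeR adjusted p = 0.0067) and RPL7B from 25.6 ± 12.1 to 97.3 ± 9.40 CPM. The list held few of the counts, 0.277, 0.292 and 0.138% in DMSO 1, 2 and 3 and 0.519, 0.513 and 0.596% in eltrombopag 1, 2 and 3. These shares are unusually low for yeast mRNA libraries and may reflect the strand setting or annotation of the counting, which are not given, so how far these counts measure the transcripts themselves is uncertain. Across the alternatives 24 (without eltrombopag 3) to 68 (DESeq2) of these genes rose. Among 106 ribosome biogenesis genes, 11 fell, 2 rose and 93 were not past the threshold, and adjusted over the list alone 9 fell and 2 rose, and the list did not pass (median -0.07, camera adjusted p = 0.263, and adjusted p = 0.878 with an estimated correlation). MAK16, a gene of the large subunit's assembly, changed by -3.08 ± 0.15. The genes that rose were NOP56 (0.95 ± 0.20) and NSR1 (1.24 ± 0.29), both nucleolar. With library size alone 0 genes of this list rose, NSR1 with an adjusted p in edgeR of 0.0516, and NSR1 also lost its call without DMSO 1 (0.0691), eltrombopag 2 (0.0506) or eltrombopag 3 (0.0611). Of 70 mitochondrial ribosomal protein genes, 7 fell, 0 rose and 63 were not past the threshold, and adjusted over the list alone 2 fell (median -0.38, camera adjusted p = 0.00207, and adjusted p = 0.736 with an estimated correlation). MRP4 changed by -1.02 ± 0.20 and RSM24 by -0.78 ± 0.13, and the list lost its call without DMSO 2 (median -0.04, camera adjusted p = 0.422). With the covariate, a fit whose p-values may be too small, 55 genes of this list fell. Proteasome genes rose by smaller amounts, with 27 of 33 up, 0 down and 6 not past the threshold, and adjusted over the list alone 28 up (median 0.52, camera adjusted p = 4.49e-09, and adjusted p = 0.175 with an estimated correlation). With library size alone only 5 of them rose (median 0.379). PRE5, a subunit of the 20S core, rose from 150 ± 14.6 to 270 ± 8.58 CPM (log2 fold change 0.84 ± 0.12, edgeR adjusted p = 0.00278).

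Drug efflux genes went both ways. In the list of drug efflux and targets of the regulator Pdr1, 4 of 23 members rose, 9 fell and 10 were not past the threshold, and adjusted over the list alone 4 rose and 10 fell (median log2 fold change -0.39, camera adjusted p = 0.198, and adjusted p = 0.736 with an estimated correlation). The list passed only without DMSO 2 (camera adjusted p = 0.0307), over a range of 0.0307 to 0.428 across the alternatives. PDR1, the main regulator of azole resistance, had 93.4 ± 16.3 CPM in DMSO and 95.2 ± 5.21 CPM in eltrombopag (log2 fold change 0.03 ± 0.15, edgeR adjusted p = 0.901). The ABC transporter gene CDR1 had a log2 fold change of -0.33 ± 0.60 (edgeR adjusted p = 0.717), with levels of 40.8 ± 22.7 and 32.3 ± 21.2 CPM that overlapped between groups. SNQ2, another ABC transporter gene, had a log2 fold change of -0.82 ± 0.36 (edgeR adjusted p = 0.124), and passed with library size alone (0.0382), the replicate block (0.0423), the covariate (0.0253) and without DMSO 2 (0.0221). The entry named PDH1 fell from 1009 ± 574 to 114 ± 12.5 CPM (log2 fold change -3.15 ± 0.51, edgeR adjusted p = 0.00513), but that symbol is used both for an ABC transporter of this species and for a baker's yeast gene of propionate metabolism. PDH1 has a coding length of 1536 bases, against 4500 for CDR1 and 4524 for SNQ2, which is too short for a full-length transporter of that kind, so it is not read here as an efflux gene, though the counts of the list include it. Among the other 8 members that fell, RSB1, a lipid translocation gene (-2.22 ± 0.47), and the ABC transporter gene YBT1 (-1.42 ± 0.34) changed most. RSB1 lost its call without eltrombopag 2 (edgeR adjusted p = 0.052) or eltrombopag 3 (0.0537), and YBT1 when any library other than DMSO 2 was left out (0.0596 to 0.0714). The members that rose were FLR2 (0.71 ± 0.19), RPN4 (0.64 ± 0.15), TPO4 (0.76 ± 0.20) and AQR1 (1.64 ± 0.40), of which AQR1 lost its call without DMSO 1 (edgeR adjusted p = 0.0605) or DMSO 3 (0.0805).

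Surface genes moved in both directions. Among 28 adhesin genes, AWP7 (1.35 ± 0.28) and EPA12 (0.91 ± 0.18) rose and AED1 (-1.19 ± 0.29) fell, also when adjusted over the list alone, and 25 were not past the threshold (median log2 fold change -0.25, camera adjusted p = 0.912, and adjusted p = 0.999 with an estimated correlation). Reads of 18 of these genes, among them AWP7, EPA12 and AED1, are shared with similar sequences. AED1 lost its call without DMSO 1 (edgeR adjusted p = 0.0634), DMSO 3 (0.0629), eltrombopag 2 (0.0843) or eltrombopag 3 (0.0809). EPA1, the main epithelial adhesin gene, had a log2 fold change of -0.26 ± 0.16 (edgeR adjusted p = 0.249). Of 10 yapsins, aspartic proteases of the cell surface, YPS6 (1.17 ± 0.20) and YPS3 (0.99 ± 0.22) rose, YPS10 (-1.59 ± 0.14), YPS9 (-1.17 ± 0.16) and YPS11 (-1.09 ± 0.13) fell and 5 were not past the threshold, and adjusted over the list alone 4 rose and 3 fell (camera adjusted p = 0.834, and adjusted p = 0.925 with an estimated correlation). Of 52 cell wall synthesis and integrity genes, 10 rose and 5 fell, and adjusted over the list alone 5 rose and 4 fell (median 0.16, camera adjusted p = 0.171, and adjusted p = 0.467 with an estimated correlation), while 4 rose and 6 fell with library size alone. Those that fell were RCN1, a calcineurin regulator gene (-1.15 ± 0.11), FKS1, a glucan synthase gene (-0.69 ± 0.11), CNB1, MNN4 and GAS2, of which GAS2 lost its call without DMSO 1 (edgeR adjusted p = 0.063), DMSO 3 (0.0537), eltrombopag 2 (0.0754) or eltrombopag 3 (0.0604). CWP1.2, a wall protein gene with shared reads, had a log2 fold change of 1.77 ± 0.23.

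**Figure D3:**
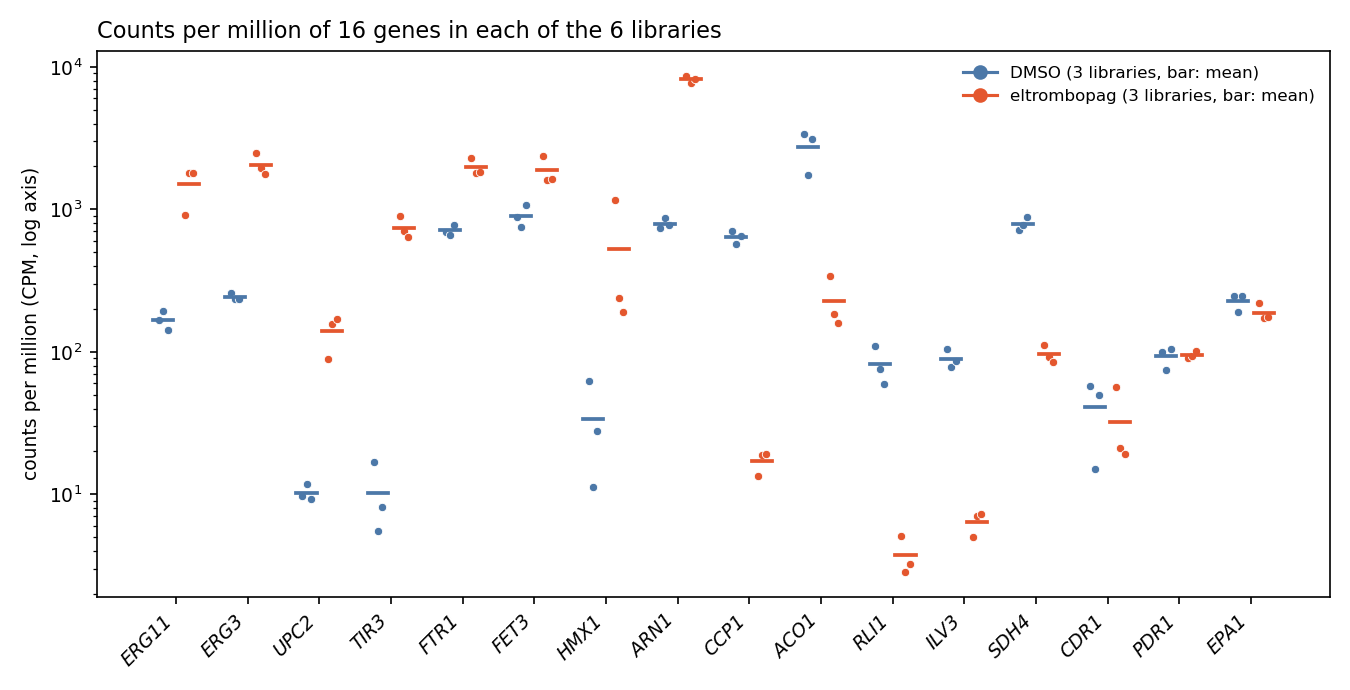
CPM (log axis) of 16 genes in each library, blue for DMSO and red for eltrombopag, with a bar at each group's mean. ERG11 lies at 143 to 192 CPM in DMSO and 909 to 1795 CPM in eltrombopag, CCP1 at 572 to 710 and 13.5 to 19.3 CPM, and CDR1, PDR1 and EPA1 overlap between groups.

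The authors' deposited table gives its own fold changes and p-values for 5281 genes. The authors' deposited table has a false discovery rate under 0.05 for 122 genes, 44 of them higher and 78 lower under eltrombopag. Of these, 121 were also called here in the same direction. The exception was GVI51_J00737, with a log2 fold change of -3.80 ± 1.60 here (edgeR adjusted p = 0.114). Fold changes here and in the authors' deposited table had a Pearson correlation of 0.995 across genes, which are not independent replicates. Both come from the same counts, so neither this correlation nor the shared calls are an independent check.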

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

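The fit with eltrombopag 2 and 3 as 1 sample and the fit with the split of the libraries as a covariate were chosen after the results were seen. Across 16 other fits of the genes, no gene called in the first analysis had the opposite sign, and no named gene or list past the threshold in either fit reversed. All fits reuse the same libraries, and groups did not overlap in 1637 of the 1643 genes called. A change of sign was therefore hardly possible, and its absence is no separate check of direction. Of the 170 named genes, 42 lost their call without eltrombopag 2, the most in any fit. Between 806 of the 1643 calls (without eltrombopag 2) and 1640 (counts not rounded, and the covariate) were called again in the same direction. With library size alone 333 genes rose, with eltrombopag 2 and 3 as 1 sample 360 rose and 476 fell, and with the covariate 1225 rose. The covariate was taken from these same counts, so p-values of that fit may be too small. Leaving out 1 library gave 350 to 959 rising genes and 456 to 938 falling genes, lowest without eltrombopag 2 and highest without DMSO 2, and each such fit has fewer samples. The cause of the shifts in these counts was not tested. DESeq2, limma-voom, RLE factors, both filters and unrounded counts kept the counts of rising, falling and at least 2-fold changed genes within 1.5 times (687 to 974, 794 to 981 and 576 to 697). Of 23 lists called by camera, 0 passed with an estimated correlation, and fry called 25 lists for movement in one direction and 40 for change in either direction. The fry test asks whether members of a list changed at all, while camera compares them with all other tested genes. With 31.7% of tested genes called, fry's counts are therefore no check on those of camera. In one direction, fry did not call the mitochondrial ribosomal proteins (fry adjusted p = 0.307), which camera called. It called 3 lists that camera did not, those of zinc (fry adjusted p = 0.0119), fatty acid and phospholipid synthesis (0.00418) and thiamine, pyridoxine, biotin and NAD synthesis (0.00993). With the replicate number as a block, 760 genes rose and 849 fell, 694 changed at least 2-fold and 21 lists passed, and the calls of TDH3, GLK1 (GVI51_F00473) and SNQ2 changed side. The numbers gave no pairing: deviations from the group means correlated at 0.54, 0.625 and -0.428 across genes for numbers 1, 2 and 3, and not every library correlated best with its own number. The lower depth of DMSO 1, 7159111 counts, limits its low genes most.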

Other observations

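All explanations and hypotheses weighed here were tested only after the patterns had been seen, apart from the counts over other splits of the libraries. Members of several other gene groups changed under eltrombopag. Of 49 DNA replication and cell cycle genes, 17 rose and 2 fell (MCM2 and CDC9), with the same counts adjusted over the list alone (median log2 fold change 0.24, camera adjusted p = 0.00276, and adjusted p = 0.467 with an estimated correlation). With library size alone 9 of them rose (median 0.076). The largest rises were those of the ribonucleotide reductase genes RNR4 (151 ± 26.4 to 1372 ± 79.7 CPM, SD, n = 3), RNR2 (347 ± 54.9 to 1997 ± 64.7 CPM) and RNR1 (548 ± 174 to 1851 ± 372 CPM), with log2 fold changes of 3.18 ± 0.17, 2.53 ± 0.15 and 1.76 ± 0.28 (SE). Of 15 trehalose and glycogen genes, 5 rose (ATH1, PGM2, GPH1, TPS1 and UGP1) and GLG1 fell, also when adjusted over the list alone (median 0.26, camera adjusted p = 0.00999, and adjusted p = 0.375 with an estimated correlation), but the list lost its call without DMSO 2 (camera adjusted p = 0.0606). Across the alternatives its median lay between 0.125 and 0.29. Of 17 vacuolar ATPase genes, 6 rose, and adjusted over the list alone 8, and 0 fell (median 0.37, camera adjusted p = 0.00283, and adjusted p = 0.247 with an estimated correlation), led by VMA10 (0.89 ± 0.15), but with library size alone only 1 rose (median 0.215). Of 10 copper genes, CTR2 (2.51 ± 0.19), ATX1 (1.63 ± 0.12), CTR1 (1.41 ± 0.16) and CCC2 (0.99 ± 0.12) rose and COX17 (-0.69 ± 0.20) fell, and adjusted over the list alone 5 rose and 1 fell (median 0.37, camera adjusted p = 0.0434, and adjusted p = 0.534 with an estimated correlation). That list lost its call without DMSO 1 (camera adjusted p = 0.0764) or DMSO 3 (0.1), with the filter of 10 CPM (0.0698), the replicate block (0.068) and the covariate (0.196). The copper list's median ranged from 0.204 to 0.637 across the alternatives. Its members ATX1 and CCC2 are also counted among the iron uptake genes that rose. Of 20 sphingolipid genes, 7 rose, led by LIP1 (1.08 ± 0.25) and SUR1 (0.89 ± 0.14), and CSH1 fell, also when adjusted over the list alone (median 0.32, camera adjusted p = 0.041, and adjusted p = 0.557 with an estimated correlation). It lost its call with DESeq2 (0.11), library size alone (0.0581, with only 1 gene rising), the filter of 10 CPM (0.074), the covariate (0.0562) and without DMSO 1 (0.103) or DMSO 3 (0.076). Single genes named here lost their calls without a library in several cases, LIP1 without DMSO 1, DMSO 3, eltrombopag 2 or eltrombopag 3 (edgeR adjusted p = 0.056, 0.0702, 0.0653 and 0.0637), GPH1 without DMSO 2, DMSO 3 or eltrombopag 2 (0.0583, 0.095 and 0.0625) and TPS1 without eltrombopag 1, 2 or 3 (0.0516, 0.0654 and 0.0623).

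The other lists did not pass with camera, and in each except the vitamin list members moved in both directions. Of 31 oxidative stress genes, 10 rose and 7 fell, and adjusted over the list alone 11 and 7 (camera adjusted p = 0.429). The thioredoxin reductase gene TRR2 (2.58 ± 0.24) and the sulfiredoxin gene SRX1 (2.10 ± 0.20) rose, and CTA1 (-3.04 ± 0.22) and GRX5 (-2.82 ± 0.27), a glutaredoxin of cluster assembly, fell. Of 24 heat shock genes, SSB1, SSA4, HSP31, CPR6 and HSF1 rose and SSC1 fell, also when adjusted over the list alone (camera adjusted p = 0.406), and reads of SSB1, SSA4 and SSC1 are shared with similar genes. Of 19 genes of the unfolded protein response, 6 rose and CNE1, HAC1 and JEM1 fell, and adjusted over the list alone 7 rose and 4 fell (camera adjusted p = 0.263), but with library size alone 0 rose and 3 fell. Zinc genes had 3 rises (FET4, ZRC1 and IZH4) and 3 falls (ZRT2, ZRT3 and MSC2) among 11, also when adjusted over the list alone (camera adjusted p = 0.999). Of 26 fatty acid and phospholipid genes, DGA1 rose and 6 fell, also when adjusted over the list alone, among them OPI1 (-1.16 ± 0.12) and the desaturase gene OLE1 (-0.81 ± 0.12) (camera adjusted p = 0.346). Of 12 stationary phase genes, SPG1 (1.75 ± 0.11) and DDR48 rose and GRE1 (-1.62 ± 0.12), GCY1 (-1.21 ± 0.12), HSP30 and MOH1 fell, also when adjusted over the list alone (camera adjusted p = 0.883). Of 26 autophagy genes, ATG32 (1.08 ± 0.11) and ATG21 rose and ATG3 (64.2 ± 1.90 to 22.8 ± 2.24 CPM), ATG12 and VPS30 fell, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.908). Of 24 mating and meiosis genes, IME2 (2.49 ± 0.15) rose and IME1 (-1.36 ± 0.20), STE7, AGA1 and STE12 (GVI51_M01155) fell, also when adjusted over the list alone (camera adjusted p = 0.264). Of 17 phosphate genes PMU2 rose and PHM8 (-1.37 ± 0.10) fell (camera adjusted p = 0.764), of 9 hexose transport genes SNF3 rose and HXT4 fell (0.616), and of 10 vitamin genes THI4 (-2.15 ± 0.43), TNA1 (-1.72 ± 0.15) and THI3 fell (0.183), each also when adjusted over the list alone. With an estimated correlation the adjusted p of these lists lay between 0.467 and 0.999. Median and mean differed in sign for oxidative stress (-0.03 and 0.06), heat shock (-0.05 and 0.11), zinc (-0.30 and 0.04) and stationary phase genes (0.09 and -0.21), and for autophagy both were below 0 (-0.01 and -0.04) while camera's direction was higher. With library size alone 0 fatty acid and phospholipid, phosphate and hexose transport genes rose, and 6 oxidative stress, 3 heat shock, 1 zinc, 1 stationary phase and 1 autophagy genes did. None of the mitochondrially encoded genes listed was measured. Without eltrombopag 2 or 3, edgeR's calls of SSA4, SSC1, HAC1, ZRC1, ZRT2, HSP30, ATG12, ATG21, PMU2, SNF3 and THI3 were lost (adjusted p = 0.0555 to 0.136), and all of these except SSA4, SSC1, ZRC1 and PMU2 lost theirs without at least 1 DMSO library too (0.0505 to 0.121), as SSC1, ATG12 and ZRT2 did without eltrombopag 1 (0.0597, 0.0741 and 0.112) and MSC2 without eltrombopag 2 (0.0505).

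The 6 libraries can be split into 3 and 3 in 10 ways, which are too few for a share under 0.05. The real split gave 777 rising, 866 falling and 656 at least 2-fold changed genes, and the highest of the other splits gave 42 genes in a direction, taken as the larger of the directions, and 41 at least 2-fold changed. Only 1 of the 10 splits, the real one, gave counts as large as these. That highest other split set DMSO 1, DMSO 3 and eltrombopag 1 against the rest, the sets that the second principal component separates. For gene lists called with the preset correlation, 3 of the 10 splits gave as many as the real one, 23. The highest other count was 23, when DMSO 1 and DMSO 3 were grouped with eltrombopag 2 or with eltrombopag 3, and the lowest was 11. In every other split the sides hold unequal numbers of DMSO libraries. The difference between treatments then lies partly between the sides and partly within them. These splits therefore do not show what counts arise without a treatment effect.

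DMSO 2, eltrombopag 2 and eltrombopag 3 stood apart from the other libraries of their groups, and 54 genes lay more than 1.5 log2 lower in them in both groups, while 0 lay that much higher. ICL1, the isocitrate lyase gene, had 705, 14.3 and 169 CPM in DMSO 1, 2 and 3 and 179, 8.08 and 6.81 CPM in eltrombopag 1, 2 and 3, and 4 of the 54 genes (GVI51_B03575, HMX1, ARO10 and HSP30) were called between groups. Whole-chromosome copy number is argued against, since no chromosome's median shift lay more than 0.061 log2 from that of all genes. The trend with coding length is argued against as the whole cause, since the correlation of the shifts across genes was 0.706 before and 0.716 after it was removed. Separate cultures, library preparations or runs could give a shared shift with that correlation of 0.706 and cannot be told apart, because the labels hold no date or run, and no biological explanation was tested.

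Ribosomal protein genes had a median of 15.9 CPM in DMSO, where 10000 lists matched on coding length had medians of 11.3 to 60 CPM, and rose by a median of 1.39 on the log2 scale. Coding length and expression level are argued against, since the highest median among 10000 lists of other genes matched on both was 0.315. Scaling is argued against as the whole cause, since the lowest median with library size alone or RLE factors was 1.237. Variation of these genes from library to library within groups remains open, because the adjusted p with an estimated correlation was 0.467 and the summed level in DMSO ranged from 1364 to 2782 CPM, against 5155 to 6089 CPM in eltrombopag. An effect of the drug on these genes remains open as well and cannot be told apart from that variation with 3 libraries per group. Whether the strand setting or annotation of the counting lowered the level of these genes was not tested.

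The authors' deposited table has 122 genes with a false discovery rate under 0.05, against 1643 called here. An exact test on the rounded mean counts of the groups, 1 against 1 with a dispersion fixed at 0.1, returned the p of 5281 of its 5281 genes within 0.1%, which is consistent with a comparison of group means that leaves out the spread between replicates. Replicate libraries with an estimated dispersion are argued against, since the same test on the 6 libraries called 1676 genes. A dispersion of 0.1 is a coefficient of variation of 31.6%, above the 21.7% estimated here. The 9 transcripts absent from that table had mean counts that rounded to 0 in both groups.

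A hypothesis is that iron in the gene product may mark the size of these changes, and it was tested with 4 one-sided permutation tests of the difference of mean log2 fold change, adjusted together, on groups of genes chosen after their values were seen. Genes within a list are not independent, so the p-values are too small by an unknown amount. In the 5 amino acid and sulfur lists together, 5 genes of iron-sulfur enzymes (GLT1, ILV3, LEU1, LYS4 and MET5) changed by -2.65 ± 1.05 (mean ± SD) and the other 74 by -1.16 ± 1.09 (permutation p = 0.00361, adjusted p = 0.00722). Genes were permuted across all these lists, so differences between lists enter that result. Mean log2 fold changes were -0.342 in the sulfur list, which holds MET5, and between -1.997 and -1.612 in the others. Whether the iron-sulfur enzymes fell further within each list was not tested. In the ergosterol list, 4 genes of iron or heme enzymes (ERG3, ERG5, ERG11 and ERG25) changed by 2.41 ± 0.98 and the other 21 by 1.43 ± 0.89 (exact permutation p = 0.0262, adjusted p = 0.0262), though ERG5 was not called between groups. CYB5, the gene of the heme protein cytochrome b5, was counted among the other 21. That test therefore concerns enzymes only and not every product of the list that holds iron. In the respiration list, 20 genes of complexes that hold iron changed by -2.42 ± 0.45 and 12 of the ATP synthase (NDI1 and NDE1 were left out) by -0.70 ± 0.44 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 4e-05). That comparison decides nothing about iron in the gene product, because most of the 20 genes encode subunits without iron. Within the 20, a test added later set 5 subunits that bind heme or a cluster (CYC1, CYT1, RIP1, SDH3 and SDH4), at -2.79 ± 0.36, against the other 15, at -2.29 ± 0.41 (exact permutation p = 0.0134, adjusted p = 0.0179), though SDH3 and SDH4 are the only genes of complex II among them. The tests do not separate iron content from other differences between these genes, such as regulators shared within each complex.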
